A study of Mus musculus with 8 samples.

How the data were processed

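The series holds 8 mouse embryonic lung RNA-seq libraries of strain C57BL/6. Ribosomes of tamoxifen-labelled cells were recovered by immunoprecipitation of the ribosomal protein L10, and libraries were made with NEBNext Ultra, per the labels' protocols. The groups were E14 TRAP, E14 whole lung, E17 TRAP and E17 whole lung with 1 library each, and E16 TRAP of the wild type and of the Sox9 mutant with 2 libraries each. Each library was placed in its group by its title, although the titles of the E16 libraries do not name TRAP.

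The authors deposited 1 table per library with an FPKM value (fragments per kilobase of transcript, scaled by the mapped fragments of the library) and its lower and upper confidence bounds for each of 24487 records, per the file headers. Reads were aligned with TopHat2 2.0.14 and Bowtie2 2.2.3 to mm10, and values were made with Cufflinks 2.2.1 and Cuffnorm, per the submitters' processing notes. How Cuffnorm set the library totals is not given in the sources used here, and the values were taken as deposited with no further scaling. The records carried 23997 gene symbols, and 750 records shared a symbol with another. Starts were counted from 0 in the deposited positions, and 1 was added: of 22897 records with a RefSeq symbol, 13565 then started at the RefSeq position, against 731 without it. Genes encoded by the mitochondrial genome were not analysed here.

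The number of fragments behind a value was computed as the square of the value over its standard error, with the distance from value to upper bound read as 2 standard errors. Among values resting on under 20 fragments, between 60.4% and 62.2% per library came out whole within 0.02 fragments. Of 12165 records with a mean of at least 1 FPKM, 8772 (72.1%) had bounds that moved between libraries by 1 common factor within 0.1 log2, as counting error alone would give. The sums were 9783768 and 21500523 fragments for E14 TRAP and whole lung, 15504704 and 16227391 for E17, 17451949 and 19102589 for the wild type and 20193311 and 17366187 for the mutant. The bounds of those 8772 records were thus read as counting error only. For the other records, which the sums include, the inferred fragments are less certain. Since fragments are inferred from the bounds, a model of counts was run only as an alternative.

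Tests were run with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), so the log2 differences understate the change of low genes. Records with a mean of at least 1 FPKM over the libraries of a fit were kept. The mutant fit used the 4 E16 libraries and had 2 residual degrees of freedom (3.73 prior). The fit of TRAP against whole lung used the 4 libraries of E14 and E17 with stage as an additive term and had 1 residual degree of freedom (4.47 prior). Both used eBayes with a trend, two-sided p-values and Benjamini-Hochberg adjustment at 0.05. Comparisons of single libraries carry no test: a record was counted where it differed at least 2-fold. A library pair was compared on fragment numbers over 8437 records to see whether replicates were 1 library deposited again. The mean squared difference in units of counting error was 5.11 between the wild-type replicates, 7.79 between the mutant replicates and 67.7 between wild-type and mutant replicate 1, so each library was kept as its own sample.

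The groups, tests, named-gene rule and 29 gene lists were fixed before the data were examined. The lists covered lung epithelial types, other cell types, signalling responses, cell cycle, ribosomal proteins, nuclear noncoding RNA, and Y-linked genes with Xist. A list was tested with at least 3 members past the filter, using camera with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, with camera at an estimated correlation and fry beside it. In the mutant 25 lists could be tested, since the leukocyte, neural and mitochondrial lists had fewer members past the filter, and the Y-linked list was kept for description. For single libraries, the median of a list was ranked among 10000 random lists matched on expression in 20 bins. Lists of liver, cardiac muscle, and stomach and intestine genes were written after the leading mutant genes had been seen. The named genes of the mutant comparison were Sox9 and the 10 with the largest change in each direction among those that passed and whose mutant values lay outside the wild-type range. In the TRAP comparison they were the 10 highest and 10 lowest with at least 5 FPKM in the higher fraction at both stages, and between stages the 10 highest and 10 lowest with at least 5 FPKM in the higher library. Up to 4 members per list with the smallest p, or the largest change where no test was run, were named too. Predicted gene models and ribosomal pseudogenes were passed over. Slc34a2 and Afp in the mutant, and Muc5ac, Agr2 and Spink4 of the added lists, were chosen after their values were seen.

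The steps were tested on simulated data, with fragments drawn from a negative binomial (dispersion 0.01) around the real levels and 200 records changed. In the simulated mutant comparison over 11770 records, 46.3% of records changed 1.5-fold were recovered, 97.0% of those changed 2-fold and 100% of those changed 4-fold, with 15 unchanged records called. In the simulated TRAP comparison over 12309 records the shares were 52.2%, 98.5% and 100%, with 50 unchanged records called. In both simulated comparisons, unchanged records made up a larger share of the calls than the adjusted p threshold of 0.05 allows. The excess was larger in the TRAP design. A list of 20 genes shifted by 0.5 log2 reached a camera adjusted p of 1.3e-28 over 11749 records of the mutant design and 5.0e-25 over 12310 records of the TRAP design, and the other simulated lists were not called. With an estimated correlation the same shifted list had an adjusted p of 0.179 and 0.983, so that form missed a known shift of this size. The simulation drew each gene independently, so it cannot show whether the preset correlation of 0.01 holds in the data. In the mutant fit the estimated correlation of the lists that camera called ran from 0.0084 for cell cycle to 0.936 for endothelial genes. It was 0.857 for ribosomal genes.

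The alternatives tried were other pseudocounts, filters, scalings, forms of eBayes, a fit of all libraries, the replicate number as a block, each replicate left out, other thresholds and fold sizes, and the wild-type E16 libraries added to the TRAP fit. Chosen after seeing the data were leaving out records that span under 200 bases, with and without rescaling, counting only changes of at least 2-fold, and limma-voom on the inferred fragments.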

Results

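The libraries profiled the Sox9 progenitors of the embryonic mouse lung. Sox9 encodes a transcription factor of the growing epithelial tips, from which the airway and alveolar epithelium arise. Translating ribosome affinity purification (TRAP) recovers mRNA from ribosomes that carry a tagged protein in a chosen cell type. Here ribosomes were pulled down through the ribosomal protein L10, and the labelling was induced with tamoxifen. The 8 libraries comprised TRAP and whole lung at embryonic day 14 (E14) and at E17, with 1 library each, and TRAP at E16 from 2 wild-type and 2 Sox9 mutant samples. The series design called the E14 reference a supernatant, whereas its own label called it whole lung homogenate, and it is named whole lung here. The titles of the E16 libraries also carry E13, which the labels do not explain. Between 9783768 and 21500523 fragments lay behind the values of a library, as computed from the deposited confidence bounds. The FPKM values of a library summed to between 659798 and 1631259. The highest total belonged to wild-type replicate 1, where the short microRNA record Mir762 held 50.05% of it. Mir762 also held 34.0% of the E17 TRAP total, and Mir5133 held 11.5% of that of mutant replicate 2. Nothing in the labels states that replicates came from separate animals, so the p-values measure only the spread between these libraries. In the comparison of TRAP with whole lung they measure only the disagreement between the stages.

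Sox9 itself (chromosome 11, 112782210 to 112787757, mm10) was read first in every library. Its level was 63.9 FPKM in E14 TRAP and 15.0 in E14 whole lung, and 68.5 in E17 TRAP and 16.7 in E17 whole lung. In the E16 TRAP libraries it was 35.9 and 36.4 FPKM in the wild type against 12.8 and 11.03 in the mutant. The mutant mean was 11.9 ± 1.25 FPKM against 36.1 ± 0.385 in the wild type (SD, n = 2 each), a 2.88-fold decrease of FPKM + 1. The log2 difference was -1.53 (SE 0.08, limma with Benjamini-Hochberg adjustment, adjusted p = 0.000153), and it was lower in 2 of 2 mutant libraries. When each library was rescaled to a common total, the difference was -1.09 and no longer passed. With records under 200 bases left out before that rescaling, the difference was -1.48 and passed. The labels do not say which part of the gene the mutation removes, so it is not known how far this record still counts transcripts of an altered gene.

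**Figure D1:**
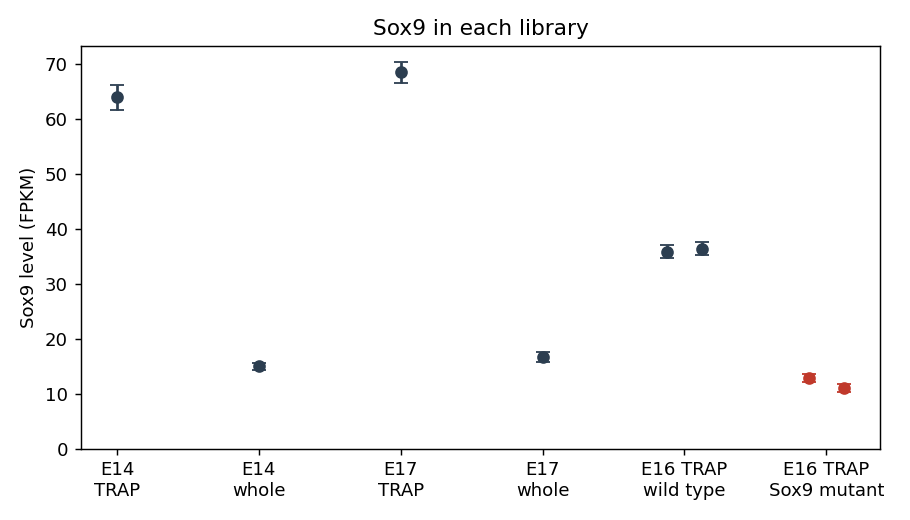
Sox9 level in FPKM (vertical axis) in each of the 8 libraries, 1 point per library, with the confidence bounds that the authors deposited as bars. Both mutant libraries (12.8 and 11.03 FPKM) lie below both wild-type libraries (35.9 and 36.4 FPKM), and both TRAP libraries of E14 and E17 lie above their whole lung.

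The comparison of mutant with wild type asked which mRNAs of the labelled cells differ when Sox9 is mutated. Sftpc, which encodes surfactant protein C, dropped from 4138 ± 494 to 169 ± 9.55 FPKM (SD, n = 2 each; log2 -4.60, SE 0.09, adjusted p = 2.0e-05). The Iroquois homeobox gene Irx1 dropped from 228 ± 9.04 to 6.71 ± 1.13 FPKM (log2 -4.90, adjusted p = 2.0e-05), and its neighbour Irx2 changed by -3.54. Etv5, an ETS transcription factor induced by FGF signalling, went from 231 ± 8.50 to 14.8 ± 1.38 FPKM (log2 -3.88). With predicted gene models passed over, the others of the 10 genes that fell most were Thbs1 (thrombospondin 1, log2 -4.09), Matn4 (matrilin 4, -4.01), Tinag, a basement membrane glycoprotein (-4.30), Cytl1 (-4.31), Fam89a (-3.76) and Cntfr, a receptor for ciliary neurotrophic factor (-3.27).

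Of the 10 genes that rose most, chosen in the same way, 8 had wild-type means of 1.65 FPKM or less. Albumin (Alb) rose from 0.328 ± 0.194 to 46.1 ± 11.5 FPKM (log2 5.13, SE 0.19, adjusted p = 6.2e-05). Other plasma protein genes rose with it, namely Trf (transferrin, log2 3.95) and Apoa1 (3.61). Tff3 and Gkn2, which encode secreted proteins of mucosal surfaces, rose by 4.64 and 4.49, with Tff3 listed at 0 in wild-type replicate 1. Myh7, the slow cardiac myosin heavy chain, rose by 3.80, Parm1 by 3.64 and the transcriptional cofactor Eya2 by 3.32. Creb3l1, a transcription factor anchored in the endoplasmic reticulum, rose from 7.39 ± 0.198 to 82.0 ± 0.418 FPKM (log2 3.31). Lypd2 rose from 24.2 ± 1.70 to 246 ± 10.02 FPKM (log2 3.30). Each of these 20 genes passed limma's test with an adjusted p of 0.000246 or less, and both mutant values lay outside the wild-type range.

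Distal tip progenitor genes fell as a group. Of 17 tested members, 10 fell, 4 rose and 3 did not pass (11 and 5 with p adjusted over the list alone), with a median log2 of -0.83. Besides Sox9 and Etv5, the members that fell included Wnt7b (log2 -2.69), a Wnt ligand of the lung epithelium, Mia (-2.13) and Id2 (-2.00), a marker of the tips. Etv4 (1.02) and Dusp6 (0.53), which like Etv5 respond to FGF signalling, rose, as did Shh (0.29). Targets and regulators of Wnt and beta-catenin signalling moved the same way, with 6 of 8 down and 1 up (the same counts over the list alone; median log2 -1.50). They included Axin2 (-2.08), Nkd1 (-1.70), Rnf43 (-1.53) and Tcf7 (-1.46). Of 12 cartilage genes and cartilage targets of SOX9, 7 fell and 2 rose (7 and 3 over the list alone; median -0.86). Col9a3 (-2.59) and Col9a1 (-2.03), chains of type IX collagen, fell with Matn4, while Matn3 rose (1.71). By camera with its preset correlation, the adjusted p over the tested lists was 0.00157 for the tip list, 0.00014 for the Wnt list and 0.0280 for the cartilage list, all downward. The cartilage call was lost without wild-type replicate 2 (median -0.57), with no filter (-0.25) and with centring (-0.91). With an estimated correlation the adjusted p was 0.626 for each of the 9 lists that camera called in this comparison. Fry asks whether a list moves one way without comparing it with other genes. By fry the tip (adjusted p = 0.0188), Wnt (0.0188), cartilage (0.0491), pan-epithelial (0.0209) and proximal airway (0.0464) lists passed. The endothelium (0.338), cell cycle (0.0706), hypoxia (0.0944) and ribosomal (0.114) lists, which camera also called, did not pass by fry.

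Airway and general epithelial genes rose. Of 12 proximal airway genes tested, 7 rose and 5 did not pass (the same over the list alone; median log2 1.40, camera adjusted p = 0.00948, and adjusted p = 0.626 with an estimated correlation). With no filter on low values the median was 0.09 and the call was lost. Scgb3a2, a secretoglobin of club cells, had 145 and 121 FPKM in the wild type and 1236 and 1372 FPKM in the mutant (log2 3.28, SE 0.10, adjusted p = 3.6e-05). The ciliated cell regulators Foxj1 (2.56) and Ccno (1.58) rose, and so did Sox2 (1.43), the transcription factor of the conducting airway. Of 23 pan-epithelial genes, 19 rose, 1 fell and 3 did not pass (the same over the list alone; median 0.46, camera adjusted p = 5.2e-08, and 0.626 with an estimated correlation). Krt19 (1.80), Prss8 (0.93) and Krt7 (0.69) rose, and Lama3, a laminin chain, fell (-1.58).

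Alveolar genes split. Of 16 alveolar type 2 genes, 8 rose, 4 fell and 4 did not pass, and of 16 alveolar type 1 genes, 8 rose, 3 fell and 5 did not pass (the same counts over each list alone). Among type 2 genes, Sftpb (surfactant protein B) rose from 152 ± 21.9 to 1148 ± 163 FPKM (log2 2.91, adjusted p = 0.000102). Cebpa, a transcription factor gene of type 2 cells, rose (1.60), as did the phosphate transporter gene Slc34a2 (2.67), a list member named here after its values were seen. Sftpc and Lgi3 (-2.83) fell. Among type 1 genes, Igfbp2 (-1.69) and Akap5 (-1.29) fell while Cav2 rose (1.28). The list medians were 0.57 for type 2 and 0.32 for type 1, and camera called neither (adjusted p = 0.0815 and 0.0973). The type 2 list was called without mutant replicate 2 (0.69), with centring (0.52) and with the replicate number as a block (0.57).

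**Figure D2:**
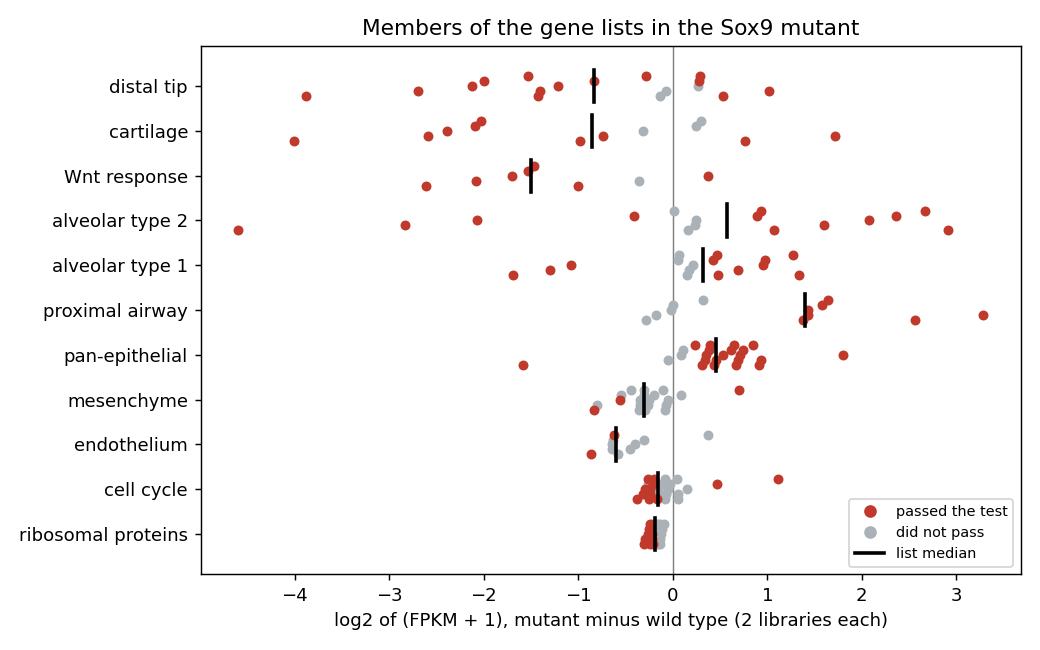
Log2 difference of FPKM + 1 between mutant and wild type (horizontal axis, means of 2 libraries each) for the tested members of 11 gene lists; each point is a gene, red where it passed limma's test, and the black bar is the list median. The distal tip, cartilage and Wnt lists have medians of -0.83, -0.86 and -1.50, and the pan-epithelial and proximal airway lists 0.46 and 1.40. The mesenchyme, cell cycle and ribosomal medians (-0.30, -0.16 and -0.19) turn positive (0.04, 0.29 and 0.27) when each library is rescaled to a common total. That rescaling moves the median of all records to 0.41.

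**Figure D3:**
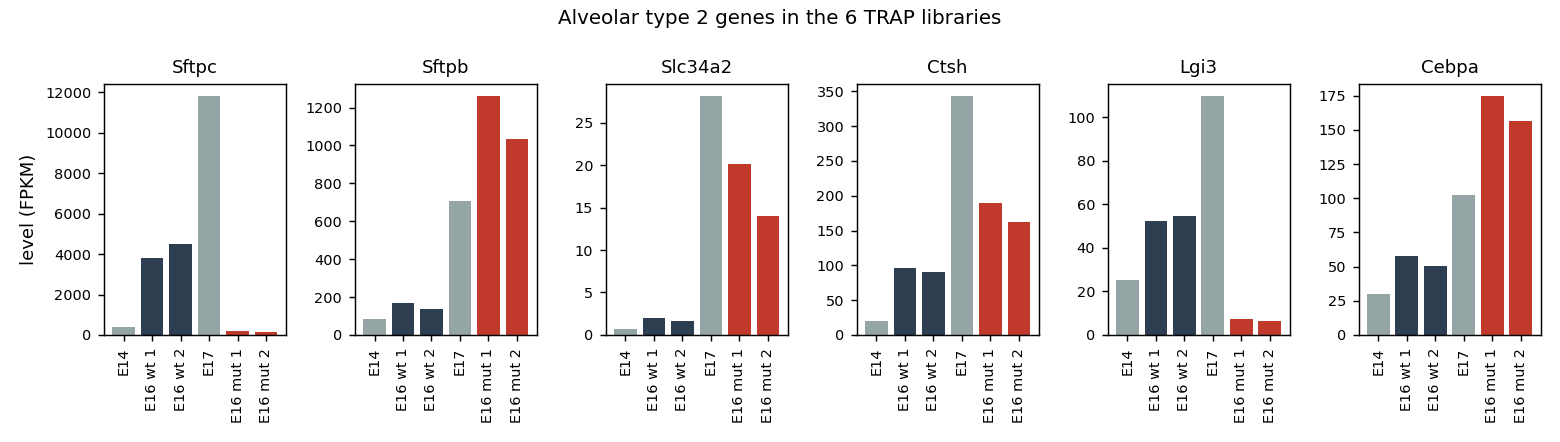
Levels in FPKM (vertical axes, starting at 0) of 6 alveolar type 2 genes in the TRAP libraries, 1 bar per library, with wild-type E16 in dark blue, mutant E16 in red and the E14 and E17 libraries in grey. Sftpc falls to 176 and 162 FPKM in the mutant, below its E14 level of 399.6, while Sftpb reaches 1263 and 1033 FPKM, above its E17 level of 709.

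Most markers of other cell types did not pass. Of 20 mesenchyme genes, 2 fell (Vim, log2 -0.84, and Foxf1, -0.56), 1 rose (Dcn, 0.70) and 17 did not pass (1 up and 1 down over the list alone; median -0.30, camera adjusted p = 0.0815), a median that turned to 0.04 when each library was rescaled to a common total and to 0.07 without mutant replicate 1. Without mutant replicate 2 or wild-type replicate 1 it was -0.58 or -0.53 and was called. Of 10 endothelial genes, Egfl7 (-0.63) and Esam (-0.87) fell and 8 did not pass (4 fell over the list alone; median -0.60, camera adjusted p = 0.0225, and 0.626 with an estimated correlation). This call was lost without wild-type replicate 2 (median -0.34), without mutant replicate 2 (-0.30), with a filter of 5 FPKM (-0.63) and with centring (-0.65). No smooth muscle or pericyte gene passed limma's test among the 7 tested, 0 had an unadjusted p under 0.05, and limma-voom called 0 of 4. Of 7 erythroid genes, 2 rose, 1 fell and 4 did not pass (the same over the list alone), with Hbb-bs up (3.02, at 9.14 and 5.57 FPKM in the mutant against 0.00292 and 0.00290 in the wild type), Hba-a2 up (0.68) and Hba-a1 down (-0.72). Globin genes have near-identical copies, so the division of fragments between them is uncertain.

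Cell cycle, glycolytic and ribosomal protein genes shifted slightly downward on the deposited scale. Of 25 cell cycle genes, 10 fell and 2 rose (13 and 2 over the list alone; median log2 -0.16, or 0.29 when rescaled to a common total). Birc5 (-0.31) and Bub1 (-0.38), which act in mitosis, fell, while the G1 cyclin genes Ccne1 (1.11) and Ccnd1 (0.46) rose. Of 13 hypoxia and glycolysis genes, 7 fell, with Egln3 (-1.06) and Ldha (-0.49) among them, and 2 rose (9 and 2 over the list alone; median -0.26, or 0.08 when rescaled). Of 35 cytosolic ribosomal protein genes, 9 fell, Rplp1 among them (-0.30), and 26 did not pass; over the list alone 0 passed limma's test, though 23 had an unadjusted p under 0.05 and limma-voom called 14 of 31 lower. The median was -0.19, or 0.27 when rescaled. Rescaling moved the median of all records to 0.41, above each of the rescaled list medians of this paragraph. The camera adjusted p values were 0.0256, 0.0177 and 2.2e-06, each 0.626 with an estimated correlation. The cell cycle call was lost without wild-type replicate 1 (median -0.12) and when records under 200 bases were left out before rescaling (-0.09), and the hypoxia call without mutant replicate 2 (-0.23).

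Over all 11872 records tested, 2063 were higher and 1692 lower in the mutant by limma with Benjamini-Hochberg adjustment at 0.05, of which 338 and 228 changed at least 2-fold. The higher records made up 54.9% of the calls, 42.8% when each library was centred on its median, 68.0% when records under 200 bases were left out before rescaling to a common total, and 75% when all records were rescaled. That last rescaling moved the median of all records to 0.41 and left 174 higher and 58 lower. Leaving out wild-type replicate 1 left 1326 higher and 882 lower, and leaving out wild-type replicate 2 left 1166 and 722.

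The comparison of TRAP with whole lung asked which mRNAs the pulldown from Sox9 progenitors holds above the rest of the organ. Epithelial genes stood out on the TRAP side at both stages. Sox9 was 3.998-fold higher in TRAP as FPKM + 1 (log2 2.00, SE 0.10, adjusted p = 0.000466; log2 2.02 at E14 and 1.98 at E17). The most enriched genes were Irx3 (log2 2.37), Mia (2.37), the tight junction gene Cldn7 (2.36), Cytl1 (2.33), Kank1 (2.33), the polarity gene Crb3 (2.31), Fam89a (2.29), Sftpc (2.22), Rnf43 (2.18) and Cym (2.15). Irx3, for instance, had 253 FPKM in TRAP against 41.5 in whole lung at E14, and 284 against 62.4 at E17. Each of the 10 passed limma's test in the joint fit of both stages, which tests neither stage alone. The adjusted p values ran from 0.000345 for Cldn7 to 0.00156 for Kank1.

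The most depleted records fell into collagens and small RNAs. Col3a1 had 9.48 FPKM in TRAP against 332 in whole lung at E14 and 10.998 against 362 at E17 (log2 -4.95, SE 0.09, adjusted p = 8.5e-05). Col1a1 had 18.7 against 273 and 12.3 against 334 FPKM (log2 -4.23). The pseudogene Atp6v0c-ps2 was also lower in TRAP (-4.44), at 0.0168 against 17.7 FPKM at E14 and 0.0145 against 24.8 at E17. Whether fragments were divided between it and its parent gene was not tested. Mir6357, Mir6340, Snora15, Mir1957b, Rmrp, Mir8099-1 and Mir8099-2 were listed at 0 in both TRAP libraries. In whole lung they had 212, 186, 122, 33.0, 28.8, 11.99 and 11.99 FPKM at E14, and no fold is given for them. All but Rmrp span under 200 bases, where few fragments can give a large FPKM, and the fragments behind their values are not given here. Mir8099-1 and Mir8099-2 had equal values in both whole lung libraries, and the division of fragments between these copies is uncertain.

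Gene lists separated the fractions by cell type. All 23 pan-epithelial genes were higher in TRAP (median log2 1.67), with Spint2 (2.12), Cldn6 (1.78) and Esrp1 (1.48), a splicing regulator of epithelia, among them. Of 17 distal tip genes, 16 were higher and 1 did not pass (median 1.59), including Wnt7b (2.12), Etv5 (1.84) and Id2 (1.62). Of 17 alveolar type 2 genes, 13 were higher and 1 lower (median 1.36), with Sftpb (2.05), Lgi3 (1.73) and Ctsh (1.70). Of 17 alveolar type 1 genes, 10 were higher, among them Igfbp2 (1.91) and Hopx (1.69), and 2 lower, including Cav1 (-2.94), which endothelium also expresses. Of 11 cartilage genes, 6 were higher and 2 lower (7 and 2 over the list alone; median 0.79), with Col9a3 (1.98) and Matn4 (1.75) up and Hapln1 down (-2.22). The camera adjusted p was 1.3e-10 for the pan-epithelial list, 5.7e-09 for the tip list, 1.1e-05 for type 2 and 0.0139 for type 1 genes, and 0.188 for the cartilage list. The type 1 call was lost with a filter of 5 FPKM (median 1.24). With an estimated correlation none of the 16 lists that camera called passed, and their adjusted p values ran from 0.524 to 0.832. By fry only the type 2 list passed among them (adjusted p = 0.0107). The adjusted p of the others by fry ran from 0.0523 for mesothelium to 0.247 for ribosomal genes.

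Markers of the other lung compartments were lower in TRAP. They included all 19 mesenchyme genes tested (median log2 -2.66; Tbx4 -3.25, Dcn -3.22 and Foxf1 -2.80) and all 17 endothelial genes (median -2.57; Cdh5 -3.90, Plvap -3.29 and Pecam1 -2.94). Depletion also covered 10 of 12 smooth muscle and pericyte genes (median -2.05; Actg2 -2.66 and Des -2.22) and 11 of 12 leukocyte genes (median -2.13; C1qc -2.54 and C1qb -2.44). It covered 9 of 10 erythroid genes (median -2.04; Alas2 -2.86 and Hbb-b1 -2.74) and 7 of 8 mesothelial genes (median -1.63; Nkain4 -3.01 and Upk3b -2.84). The camera adjusted p values of these 6 lists ran from 1.4e-14 for mesenchyme to 0.000115 for mesothelium (0.524 for each with an estimated correlation). The hedgehog list divided by cell type, with Shh, the epithelial ligand, higher in TRAP (1.66) and 5 of its 7 members lower (6 over the list alone), among them the mesenchymal effectors Gli1 (-1.95) and Gli2 (-1.80). Of 7 noncoding nuclear RNAs, which are not translated, 5 were lower (6 over the list alone; median -1.83), including Rian (-3.39) and Malat1 (-1.83). For the other lists of this paragraph, and for the epithelial, tip and alveolar lists, the counts over the list alone were the same.

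**Figure D4:**
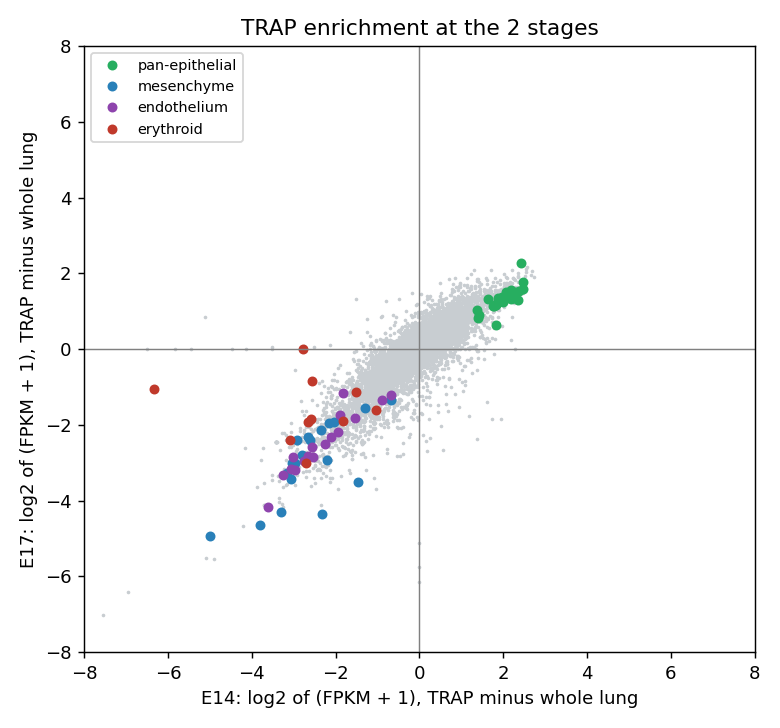
Log2 difference of FPKM + 1 between TRAP and whole lung at E14 (horizontal axis) and at E17 (vertical axis), 1 point per record tested, with 4 marker lists in colour and 11 records outside the axes. The pan-epithelial genes lie in the upper right (medians 2.00 at E14 and 1.32 at E17) and the mesenchymal genes in the lower left (medians -2.67 and -2.94).

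Of 12320 records tested over both stages, 2910 were higher and 2105 lower in TRAP by limma with Benjamini-Hochberg adjustment at 0.05, and 589 and 1064 of these differed at least 2-fold. The residual of this fit had 1 degree of freedom. It is the disagreement of the ratios between the stages and not a spread of replicates. In the simulated TRAP comparison, unchanged records made up a larger share of the calls than the 0.05 threshold allows. The higher records made up 58.0% of the calls, 46.9% when records under 200 bases were left out before rescaling to a common total, and 15.3% when all records were rescaled, which moved the median of all records to -0.31. Taken by stage, with 1 library on each side and no test, 742 records were at least 2-fold enriched and 1163 at least 2-fold depleted at E14, and 598 and 1126 at E17. Among the 12320 records, 419 were enriched at both stages, where independent lists would share 35.7, and 836 were depleted at both, where independent lists would share 104. Only 8 went opposite ways at that size. Across these genes, which are not independent replicates, Pearson's r of the log2 ratios was 0.74 and Spearman's rho 0.84.

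The comparison of E17 with E14 TRAP asked how the labelled cells differ between the stages. With 1 library per stage there was no replicate check and no test. Alveolar list genes were 3 of the 10 highest named records. Sftpc had 399.6 FPKM at E14, 4138 in the wild-type E16 libraries and 11835 at E17 (log2 4.88 from E14 to E17). Napsa, a protease that processes surfactant proteins, had 1.77, 9.88 and 81.7 FPKM (4.90), and Slc34a2 had 0.677, 1.80 and 28.2 FPKM (4.12). Tmem213 (5.11), S100a14 (4.38) and the chloride channel family gene Clic3 (4.10) were also among the highest. Of 17 alveolar type 2 genes, 14 were at least 2-fold higher at E17 (median log2 2.08), and of 17 type 1 genes, 13 were (median 1.59). Ctsh (4.04), Hopx (3.43), Emp2 (3.05), Clic5 (2.78) and Ager (2.48), a receptor of type 1 cells, were among them. Whole lung differed by similar amounts, with medians of 2.06 for type 2 and 1.41 for type 1 genes, 5.50 for Sftpc and 5.33 for Tmem213.

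Genes lower at E17 included Hmga2, which encodes a chromatin protein and had 132 FPKM at E14 and 37.9 at E17 (log2 -1.77). Crabp2, which encodes a retinoic acid binding protein, had 31.2 and 2.79 FPKM (-3.09), Ly6h 66.0 and 6.91 FPKM (-3.08), and Sox2 12.8 and 4.40 FPKM (-1.35). The cartilage collagen gene Col2a1 had 24.4 and 4.83 FPKM (-2.13), whereas Col9a1 had 5.04 and 13.0 FPKM (1.21). The globin genes of the early embryo, Hbb-y (-3.10), Hbb-bh1 (-3.73) and Hba-x (-2.48), were lower in E17 (Hbb-y by -5.87 in whole lung) and the fetal and adult globin gene Hbb-b1 was higher (2.11). Hbb-bs had 0.00621 FPKM at E14 and 80.6 at E17, but near-identical copies make the division between globin genes uncertain. The smooth muscle genes Actg2 (-1.82), Cnn1 (-1.78) and Acta2 (-1.54) were lower. The endothelial genes Sox18 (1.26) and Pecam1 (1.16) were higher. Smooth muscle, endothelial and erythroid genes were depleted in TRAP, and whether their differences lie in the labelled cells was not tested. Whole lung fell by -3.16 for Crabp2 and by -1.71 for Ly6h, and Acta2 differed there by 0.21. With the change in whole lung subtracted, Hmga2 (0.75), Col2a1 (0.40) and Sox18 (-0.0082) turned sign. Sox9 differed by 0.10.

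Other extremes of this comparison were short or overlapping records. Mir762 and Mir130c were listed at 0 at E14 and had 355945 and 8212 FPKM at E17. Mir1905, Mir2861 and Mir8092 had 32913, 16456.5 and 5321.5 FPKM at E14 and were listed at 0 at E17, as was Snhg9 (7.05 FPKM at E14). The microRNA records named here span under 200 bases, where few fragments can give a large FPKM. The fragments behind them are not given here, so their differences may rest on few fragments. The overlapping genes Eif3j1 and Eif3j2 went opposite ways (log2 5.37 and -3.39), and the division of fragments within this pair is uncertain. Apoo-ps was lower at E17 (-3.44). In all, 561 of 11810 records were at least 2-fold higher and 225 at least 2-fold lower at E17, of which 289 and 49 showed that size of change in whole lung too. Rescaling to a common total moved the median of all records to -0.44 and gave 268 and 966.

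The genes that differed between stages were then followed into the mutant, in libraries that the stage comparison did not use. Of 530 tested genes at least 2-fold higher at E17, 239 were higher and 89 lower in the mutant (median log2 0.26). Of 198 tested genes at least 2-fold lower at E17, 31 were higher and 81 lower (median -0.30). That median turned to 0.30 when rescaled to a common total, where the median of all records was 0.41. By camera the p values were 2.8e-06 upward and 3.3e-07 downward (adjusted over 4 sets, 5.7e-06 and 1.3e-06), and 0.0868 and 0.263 with an estimated correlation. Across 11502 genes, which are not independent replicates, the stage difference and the mutant difference had a Pearson's r of 0.14 and a Spearman's rho of 0.22. Sftpb, Slc34a2 and Cebpa were higher both at E17 and in the mutant, whereas Sftpc and Lgi3 were higher at E17 and lower in the mutant.

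The last comparison asked whether genes that TRAP enriches or depletes moved in the mutant as groups. Of 585 tested genes at least 2-fold enriched in TRAP, 165 were higher and 207 lower in the mutant (median log2 -0.05, mean -0.24). Of 682 at least 2-fold depleted, 139 were higher and 81 lower (median -0.07, mean 0.01). Camera gave p = 0.0257 downward for the enriched genes (adjusted p = 0.0343) and p = 0.818 for the depleted genes, and 0.355 and 0.963 with an estimated correlation. The median of the enriched genes was 0.02 when records under 200 bases were left out before rescaling to a common total, and 0.36 when all records were rescaled. The median of all records was 0.07 and 0.41 under these scalings. The call on the enriched genes was lost without wild-type replicate 1 (median -0.03), without mutant replicate 2 (-0.04), with a pseudocount of 0.1 (-0.04), with a filter of 5 FPKM (-0.03) and with centring (-0.09), while genes at least 4-fold enriched had a median of -1.06.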

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

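The tests of erythroid genes, of surfactant genes against stage and of ribosomal genes between stages were chosen only after the results were seen, while those of liver genes, epithelial share and transcript length were written after the patterns had been noticed but before the values they rest on.

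Some effects went opposite ways in 2 groups under the same contrast, and none of these differences was tested, since each rests on 1 library per group. The proximal airway list had a median log2 ratio of TRAP to whole lung of 0.34 at E14 and of -0.50 at E17. From E14 to E17, Acta2 differed by -1.54 in TRAP and by 0.21 in whole lung. The overlapping genes Eif3j1 and Eif3j2 differed by 5.37 and -3.39 in TRAP, against -0.58 and 0.20 in whole lung. In TRAP they had 0.115 and 55.7 FPKM at E14 and 45.1 and 4.42 FPKM at E17, and the division of fragments within this pair is uncertain. Mir130c, listed at 0 in E14 TRAP and E17 whole lung, differed by 8212 FPKM in TRAP and by -6636 FPKM in whole lung. Mir130c spans under 200 bases, where few fragments can give a large FPKM. The fragments behind its values are not given here, so these differences may rest on few fragments. The list of noncoding nuclear RNA had a median of 0.19 in TRAP and -0.21 in whole lung, and the TRAP median turned to -0.10 when rescaled to a common total.

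Genes of plasma proteins that the liver makes in bulk rose in the mutant, where Alb, Trf, Apoa1 and Afp had means of 46.1, 33.1, 19.7 and 12.4 FPKM. Liver RNA carried into these libraries would bring the other abundant liver transcripts along, but the 3 other measured members of the liver list, Apoa2 (-0.57), Apoc1 (-1.27) and Rbp4 (0.77, so 1 of them rose), which the wild type also expressed, had a median log2 difference of -0.57 (between -0.70 and -0.44 with each library left out in turn). Of 22 members, 14 stayed under 1 FPKM in all 4 libraries, among them Ttr (mutant mean 0.0626), Fga (0.0136), Ahsg and Apob, which argues against liver tissue as the source. Blood RNA in the mutant libraries cannot be told apart from the absence of it, since the erythroid median of 0.016 (from -0.09 to 0.12 with each library left out) covers members that went both ways (Hbb-bs 3.02, Hba-a1 -0.72), and haemoglobin mRNAs were already abundant in the wild type. Expression of some of these genes by labelled cells of the mutant also stays open and was not tested.

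Surfactant genes parted in the mutant, with Sftpc at log2 -4.60 against Sftpb at 2.91 and Slc34a2 at 2.67. A lower share of labelled epithelium with more mesenchymal background RNA would lower epithelial against mesenchymal genes, but the pan-epithelial median (0.46) stood above the mesenchyme median (-0.30, or 0.04 when rescaled to a common total) by 0.76, and by 0.41 to 1.02 with each library left out. Background from unlabelled epithelium would carry pan-epithelial genes too, so these lists cannot test for it. Proximal airway genes rose in the mutant (median 1.40). A shift toward the later stage as the cause of the fall of Sftpc is argued against, since Sftpc was higher at E17 than at E14 by 4.88 in TRAP and by 5.50 in whole lung, with 1 library each. For Sftpb and Slc34a2, which were higher at E17 by 3.07 and 4.12, 2 of 2 signs matched, but they were picked because they rose, so such a shift and another cause of their rise cannot be told apart.

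Ribosomal protein mRNAs stood higher in the wild-type E16 TRAP libraries than in the E14 and E17 TRAP libraries, in 35 of 35 list members and by a median log2 of 0.72, and the mutant libraries stood higher by 0.51. If short transcripts had been measured differently in the 2 sets of libraries, other genes of like effective length would differ as well, but the 100 nearest in length had a median difference of 0.09, a ratio of 0.122 to the list's own, against a median of -0.03 over all genes. A steady change with stage would place E17 beyond or beside E16, but the E17 to E14 difference was 0.03, a ratio of 0.0368 to the E16 to E14 difference of 0.71. A peak at E16 and a difference between the sets of libraries, such as how the pulldowns were made, both stay open, since no stage was sampled in both sets and the labels give no batch.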

How the results depend on the processing

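Leaving out records under 200 bases (with or without rescaling), the count of at least 2-fold changes and limma-voom on the inferred fragments were tests chosen only after the results were seen, and the count model planned for whole reads was run in that last form. Outside the 2 rescalings of all records to a common total, 84 of 93 named mutant genes, 70 of 70 named TRAP genes, 15 of 16 followed list medians in TRAP and 4 of 12 followed in the mutant (distal tip, Wnt, pan-epithelial and ribosomal genes) kept their direction and, where tested, their side of the threshold under each alternative that gave a value. The lists followed in TRAP include cartilage and proximal airway, which camera did not call, and leave out cell cycle and hypoxia, which it called. Outside the same 2 rescalings, camera's call in the mutant was lost for cartilage without wild-type replicate 2 (median -0.57), with no filter (-0.25) and with centring (-0.91), for endothelium without wild-type replicate 2 (-0.34), without mutant replicate 2 (-0.30), with a filter of 5 FPKM (-0.63) and with centring (-0.65), for hypoxia without mutant replicate 2 (-0.23), for the cell cycle without wild-type replicate 1 (-0.12) and with records under 200 bases left out before rescaling (-0.088), and for the proximal airway with no filter (0.094). A call was gained for alveolar type 2 genes without mutant replicate 2 (0.69), with centring (0.52) and with replicate as a block (0.57), and for mesenchyme without mutant replicate 2 (-0.58), without wild-type replicate 1 (-0.53), with replicate as a block (-0.30) and with records under 200 bases left out before rescaling (-0.26). The erythroid list was called when all records were rescaled (0.47). Only 12 lists were followed one by one in the mutant. Camera called 11 lists in the fit of all 8 libraries and 12 with replicate as a block, against 9 in the main fit. Lists that were not followed were thus called there, and under other alternatives too, and which ones is not given here. In TRAP the call on alveolar type 1 genes was lost with a filter of 5 FPKM (1.24). The cell cycle and hypoxia lists, which were not followed one by one in TRAP, lost their calls there too, as called lists fell from 16 to 13. With the wild-type E16 libraries added 15 lists were called, although no followed list changed its call. Between stages, 12 of 47 named genes kept their direction and their side of 2-fold, and 39 did when the subtraction of whole lung was also set aside. Sox9 stayed lower in the mutant throughout (log2 from -1.63 to -1.43 with each replicate left out). Limma-voom on 8437 records gave 1639 higher and 1185 lower, and 2397 of the 2579 genes called on FPKM among them were called with the same sign (Pearson's r of the log2 differences 0.98). With the replicate number as a block, a pairing the labels do not state (correlation of deviations 0.0072), 1929 were higher and 1574 lower. The shallowest library, E14 TRAP, had a median of 390 fragments per expressed record against 851 in E14 whole lung, so depth limits small changes of low genes most at E14.

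Rescaling each library to a common total changed many results, because by its construction the short records that held up to 53.5% of a total then set the scale of all others. It moved the median of all records to 0.41 in the mutant, to -0.31 in TRAP and to -0.44 between stages. It gave 559 higher in TRAP, 174 higher and 58 lower in the mutant, 110 enriched and 2413 depleted at E17, and 268 higher and 966 lower between stages. Sox9 in the mutant (-1.09) no longer passed. Birc5 (0.15), Bub1 (0.031), Rplp1 (0.16) and B2m (0.21) turned positive, as did the mutant medians of mesenchyme (0.041), cell cycle (0.29), hypoxia (0.078) and ribosomal genes (0.27), of genes lower at E17 (0.30) and of genes enriched (0.36) or depleted (0.38) in TRAP. Each of these values stayed below the rescaled median of all records in the mutant (0.41). With haemoglobin genes also left out the values were 529 and 3359 in TRAP, 171 and 57 in the mutant, Sox9 -1.09, 96 and 2598 at E17, 264 and 975 between stages, Birc5 0.15, Bub1 0.031, Rplp1 0.16, B2m 0.22, mesenchyme 0.041, cell cycle 0.29, hypoxia 0.079, ribosomal genes 0.27, genes lower at E17 0.30, and enriched and depleted genes 0.37 and 0.39. With records under 200 bases left out before rescaling, 2753 were higher and 1295 lower in the mutant and Sox9 was at -1.48. The enriched and depleted genes were positive there at 0.022 and 0.030, against a median of all records of 0.073. The correlation of TRAP ratios between stages was 0.86 without these records, and 0.85 with rescaling too.

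The shift of TRAP-enriched genes in the mutant depended on the setting. Their median was -0.038 with a pseudocount of 0.1, -0.034 with a filter of 5 FPKM and -0.095 with centring, each no longer called, and between -0.075 and -0.032 with each replicate left out (the call was lost without wild-type replicate 1 and without mutant replicate 2). That of depleted genes ran from -0.13 to 0.047 with each replicate left out, at 0.047 without mutant replicate 1 and 0.021 without wild-type replicate 2, and passed, among the alternatives run, only at -0.22 for sets of at least 4-fold depletion. For sets of at least 4-fold enrichment the median was -1.06 and was called. The cause was not tested.

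Counts changed with fewer libraries or other thresholds. With each replicate left out, where a lone library is assumed to vary like the other group, 1166 to 1716 were higher and 722 to 1720 lower in the mutant, the lowest without wild-type replicate 2 (1166 and 722) and next without wild-type replicate 1 (1326 and 882). Counting only 2-fold changes left 338 and 228. With a pseudocount of 5, which shrinks low genes, 364 were enriched and 488 depleted at E14, 299 and 536 at E17, and 236 higher and 71 lower between stages. A filter of 5 FPKM, which tests fewer genes, gave 1267 lower in TRAP, 615 depleted at E14 and 621 at E17, and 366 higher and 131 lower between stages. At 4-fold the counts were 100 and 324 at E14, 11 and 360 at E17, and 98 and 28 between stages. The erythroid median in the mutant was -0.025 with the 5 FPKM filter, -0.032 with centring and between -0.091 and 0.12 with each replicate left out (-0.091 without wild-type replicate 1, -0.029 without mutant replicate 2), and the mesenchyme median ran from -0.58 to 0.068 (without mutant replicate 1). The cause of these sign changes was not tested.

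With the change in whole lung subtracted, 95 records were at least 2-fold higher at E17, and genes that changed more in whole lung than in TRAP turned sign by construction: Sftpc (-0.61), Ager (-0.96), Clic3 (-0.53), Clu (-0.45), Hopx (-0.38), Egln3 (-0.28), Tmem213 (-0.22), Clic5 (-0.12), Ctsh (-0.066), Sox18 (-0.0082), Crabp2 (0.071), Col2a1 (0.40), Hmga2 (0.75), Hba-x (1.72), Hbb-bh1 (1.80) and Hbb-y (2.77).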

Other observations

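The tests of the liver, cardiac muscle, and stomach and intestine lists were chosen after the leading mutant genes had been seen.

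Signalling lists not described so far were mixed in the mutant. Of 12 FGF and ERK response genes, 5 rose and 1 fell (the same over the list alone): Spry1 (log2 0.96), Etv4 (1.02) and Dusp6 (0.53) rose while Etv5 fell (-3.88), and the median was 0.33 with a mean of 0.00. Of 10 Notch pathway genes, 4 rose and 1 fell (the same over the list alone; camera adjusted p = 0.0553, and 0.626 with an estimated correlation), with the ligand genes Jag1 (1.52) and Jag2 (0.79) and the target Nrarp (0.80) up. Of 10 BMP and TGF-beta response genes, 4 rose and 3 fell (the same over the list alone; median 0.12), where Id4 (2.65) and Id1 (1.37) rose and Id2 (-2.00) and the antagonist Nog (-1.20) fell. Of 5 hedgehog genes, Shh rose (0.29) and 2 fell, Gli1 among them (-0.61; the same over the list alone), and the median of -0.33 turned to 0.03 when rescaled to a common total. Of 10 immediate early and heat shock genes, 6 rose and 1 fell (6 and 2 over the list alone; median 0.47): Junb (1.41), Fos (1.39) and Zfp36 (1.01) rose and Jun fell (-1.10), as limma with Benjamini-Hochberg adjustment called them.

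Matrix and metabolic lists went both ways in the mutant. Of 21 basement membrane genes and receptors, 6 rose and 6 fell (6 and 8 over the list alone): the integrin gene Itgb4 rose (log2 1.81) and the laminin chains Lamb1 (-0.76) and Lamc1 (-0.86) fell, with a median of -0.12 that turned to 0.33 when rescaled to a common total. Of 17 lipid and sterol synthesis genes, 5 rose and 4 fell (5 and 6 over the list alone), with Gpam (0.74) and Acly (0.50) up and Scd1 down (-1.16), and the median of -0.08 (0.33 rescaled) and mean of 0.02 differed in sign. Of 12 genes of the unfolded protein and amino acid response, 4 fell and 1 rose (5 and 1 over the list alone): Pdia4 (-0.55) and Asns (-0.77) fell and Sesn2 rose (0.67), with a median of -0.18 (0.28 rescaled). Of 5 interferon and MHC class I genes, B2m fell (-0.24, or 0.21 rescaled) and 4 did not pass (the same over the list alone). Of 4 mesothelial genes, Msln rose (2.89) and Rspo1 fell (-0.86), with 1 and 2 over the list alone, and the median of -0.27 (0.29 rescaled) differed in sign from the mean of 0.37 and from camera's direction, which was up. Of 4 noncoding nuclear RNAs, Meg3 (0.74) and Rian (0.49) rose (2 up and 1 down over the list alone). In the main fit camera called none of these lists in the mutant (adjusted p from 0.0553 for Notch to 0.984 for mesothelium). They were not followed one by one through the alternatives, under some of which lists that were not followed were called. Fry, which asks whether a list moves one way without comparing it with other genes, gave adjusted p values from 0.0442 to 0.787, under 0.05 for the mesothelium, immediate early, noncoding, Notch and hedgehog lists. The rescaled medians given here lie below the rescaled median of all records (0.41).

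Further lists parted TRAP from whole lung. Of 25 cell cycle genes, 11 were higher and 1 lower (median log2 0.26, which turned to -0.12 when rescaled to a common total), Birc5 (0.61) and Mcm7 (0.56) among the higher. Of 14 hypoxia and glycolysis genes, 7 were higher (median 0.38), with Hk2 (1.20) and Ldha (0.73). Of 35 ribosomal protein genes, 9 were lower and 1 higher (median -0.24), and Rpsa (-0.98) and Rplp0 (-1.11) led. Of 11 Notch genes, 7 were lower (median -0.60), including Heyl (-2.62) and Notch2 (-1.21). Among 22 basement membrane genes, 11 were higher, such as the integrin gene Itga3 (1.41), and 3 lower, among them the nidogen genes Nid1 (-3.71) and Nid2 (-3.36). The Wnt list had 3 of 10 up, with Sp5 (1.57), and 3 down, with Tcf7 (-1.29), and the immediate early list 3 of 10 up, with Jun (1.98), and 2 down. The FGF list had 4 of 14 up and 4 down, Egr1 among the latter (-1.63), the BMP list 3 of 11 up and 1 down, the lipid list 5 of 17 up and 1 down, the unfolded protein list 4 of 12 up and 2 down, the interferon list 1 of 5 up and 2 down, and the proximal airway list 1 of 11 down. Over the list alone, the FGF list had 6 up, the unfolded protein list 5 up and 3 down, the Notch list 1 up, and the airway gene did not pass, while the counts of the other lists of this paragraph were the same. Camera called the ribosomal (adjusted p = 0.000407), Notch (0.0154), cell cycle (0.0261) and hypoxia (0.0299) lists among these, with adjusted p values from 0.524 to 0.832 at an estimated correlation. The ribosomal call was lost under both rescalings of all records (medians -0.63 and -0.67). The cell cycle and hypoxia calls were lost there and with a filter of 5 FPKM, since the called lists fell from 16 to 13 in each.

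Between the E14 and E17 TRAP libraries, without a test, 3 of 10 BMP response genes were at least 2-fold higher at E17, namely Id1 (log2 2.11), Smad9 (1.13) and Id3 (1.08) (list median 0.48, or -0.09 when rescaled to a common total). The lipid list had a median of -0.46, with Elovl6 at -1.91. Ndrg1 (2.58) and Egln3 (1.41) of the hypoxia list were higher, as were Junb (1.56) and Zfp36 (1.23), and Ccnd1 was lower (-1.10). The tip gene Clu was higher (1.33).

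The added stomach and intestine list had 6 members past the filter, of which 5 rose in the mutant by limma (the same over the list alone; median log2 2.81). Besides Tff3 and Gkn2, they were Muc5ac, with 0.0988 and 0.0331 FPKM in the wild type and 2.36 and 2.56 in the mutant, Agr2, with 0 and 0.137 against 2.94 and 6.69, and Spink4, listed at 0 in the wild type against 5.35 and 13.3. Mucous cells of the airway also express several of these genes. Of 7 liver list members tested, 5 rose and 2 fell (the same over the list alone), and of 5 cardiac muscle genes, Myh7 rose and 4 did not pass.

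The sex-linked genes differed between replicates of the wild type. Eif2s3y, a Y-linked gene, had 14.01 FPKM in wild-type replicate 1 and 0.0745 in replicate 2, and 0.0919 and 0 in the mutant libraries. Xist, which is expressed from the inactive X chromosome, had 0.0179 FPKM in wild-type replicate 1, 1.03 in replicate 2, and 1.02 and 1.24 in the mutant. By these values the wild-type replicates came from different embryos, whereas the mutant replicates cannot be told apart by them. The E14 and E17 libraries had between 9.09 and 14.3 FPKM of Eif2s3y and no more than 0.0986 of Xist. Genotype and sex thus overlap in part, and the counts without wild-type replicate 1 (1326 higher and 882 lower) come from libraries with 0.0919 FPKM of Eif2s3y or less.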
